A study of Mus musculus with 32 samples.

How the data were processed

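The labels describe 32 samples of mouse bone marrow, sorted by flow cytometry and processed by CEL-seq2 for single-cell RNA sequencing, 16 with the genotype wild type and 16 with mof +/-. The submitters' processing notes name BWA 0.6.2-r126 and the mm10 genome. The 40 deposited tables analysed here are plate layouts. Per the file headers, they give the well, the primer, the sorted population, the gate and the genotype, as text and well numbers. How the authors filled them in is not stated, and no deposited value in them is an expression measurement. Blank lines between wells were dropped, and every column was read, with 0 columns left unused.

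The genotype of a layout was taken from its own genotype column, with wt and WT read as wild type and Mof -/+ as Mof +/-. Layouts were not matched to single samples, because they hold no measured value per sample. The 16 het layouts carry the same names as the 16 mof +/- samples, while no source ties the wt numbers of the wild-type layouts to the control numbers of the wild-type samples. A line was counted as a well when it listed a primer. The barcode was taken as the 6 bases after the 6 N of the primer, and every listed primer had to consist of the same adapter, 6 N, 6 bases, 24 T and a V. The same gate written in different ways was recognised from its list of markers, without regard to order and spaces.

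Before the data were examined, tests of genes, gene lists and shares of cell classes between the genotypes were planned for gene counts, with barcode design results for the case that the tables held barcodes. The tables hold no gene counts, so the tests of genes were not run, no gene was named from the data by the planned rule, and the depth of the samples was not analysed. The planned barcode results are the number of barcodes per layout, the sharing of barcode sets, the Hamming distance between barcodes and the base composition. The two-sided permutation test with 100000 resamples planned for the number of barcodes per layout was run. It was also run on the GC content per layout. It decides nothing for the number of primers or for GC content, because the values per layout fix its outcome. No p-value is given for them. The limit that a count of 0 allows is 3 counts out of the wells listed, an approximate upper limit at 95% confidence. The expected number of distinct molecular identifiers assumes equal use of all 4096 sequences. The results were also computed with distinct barcodes only, numbered layouts only, matching with 1 mismatch or with the reverse complement, edit distance, pooling of all layouts, and counting each distinct barcode 1 time per genotype. Choices made after seeing the data were counting lines without a primer, leaving out the layout that lacks primers (for the number of primers and for base shares), and the distances in the stem cell layouts.

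The functions and permutation tests were tested on simulated data, and 14 of 14 checks passed. For the permutation test of means per layout, only the sign of the difference was checked, not its p-value. With 192 simulated barcodes placed at random, the test of sequence similarity against population gave p under 0.05 in 1 of 20 placements. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.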

Results

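Single cells from mouse bone marrow were sorted by flow cytometry and processed by CEL-seq2, per the labels. The labels describe 32 samples, of which 16 were wild type and 16 were Mof +/-, that is, heterozygous for Mof. The series title names MOF, a histone acetyltransferase that acetylates histone H4 and is encoded by Kat8, in erythroid fate together with RUNX1 and GFI1b, both transcription factors of blood development. What was measured here is the sort and barcode design: 40 plate layouts that give, well by well, the reverse transcription primer, the sorted population, its gate and the genotype. Gene expression and the sequencing depth of each sample were not analysed here, so no gene is reported as higher or lower in either genotype. Of the 40 layouts, 20 named wild type and 20 named Mof +/-. They fall into 32 numbered layouts (16 per genotype), 4 stem cell layouts (2 per genotype) and 4 progenitor layouts (2 per genotype). The 8 stem cell and progenitor layouts carry names that match no sample title, and they were not tied to a sample. Layouts are plans of a sort, not measurements, so values within a layout carry no replicate error, and every well was counted as listed, whether or not it gave a cell.

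The first comparison asks which populations were sorted from each genotype, and in what proportion. In the numbered layouts both genotypes had the same plan, well for well, in 32 of 32 layouts. Each held 192 wells and 5 populations that run from mixed progenitors to the stem cell gate. Kit high cells (Lin-Sca-1-cKit high), the compartment of committed myeloid and erythroid progenitors, filled 48 wells per layout, or 768 wells per genotype. LSK high cells (Lin-Sca-1+cKit high), the compartment that holds stem cells and multipotent progenitors, also filled 48 wells per layout and 768 per genotype. LSK low cells (Lin-Sca-1+cKit low) filled 36 wells per layout and 576 per genotype. The population called eHSC, gated as LSK cells without Flt3 and CD34, filled 36 wells per layout and 576 per genotype. HSC, gated in addition as positive for CD150 and negative for CD48, filled 24 wells per layout and 384 per genotype. The shares were therefore 25% Kit high, 25% LSK high, 18.75% LSK low, 18.75% eHSC and 12.5% HSC in wild type and in Mof +/- alike, with 3072 wells per genotype. These shares were set by the sorter's plan, so they do not measure how frequent a population is in the marrow of either genotype.

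The stem cell layouts were enriched for the stem cell gate. HSC filled 144 of 192 lines per layout and LSK cells filled 48, which gives 288 HSC lines and 96 LSK lines in each genotype. The 4 stem cell layouts were identical to each other. In each, 96 barcodes were listed 2 times with the same population, so the lines correspond to 144 HSC and 48 LSK barcodes per genotype when each barcode of a layout is counted 1 time.

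The progenitor layouts held the stem cell gate and populations with names from the erythroid, megakaryocyte and granulocyte-macrophage lineages. Per full layout of 192 lines, 60 were LT-HSC, 24 each were preMEP, preCFU, MEP and proE, and 12 each were MkP, GMP and preGMP. By name, preMEP and MEP are precursors of megakaryocytes and erythroid cells, and MkP cells are megakaryocyte progenitors. PreGMP and GMP cells, also by name, lead to granulocytes and macrophages. PreCFU cells were gated as CD105 positive. ProE cells were gated as Ter119 positive but negative for CD71 and CD44, and MkP cells as CD41 positive but CD150 negative. Whether the gates select the cells that the names give was not tested. Wild type had fewer lines with a primer than Mof +/- in every one of these 8 populations, by the same ratio of 0.75. In 1 progenitor layout of each genotype, 96 barcodes were listed 2 times with the same population, and with each barcode of a layout counted 1 time the ratio was 0.667. LT-HSC had 90 lines in wild type and 120 in Mof +/-. PreMEP, preCFU, MEP and proE each had 36 lines in wild type and 48 in Mof +/-. MkP, GMP and preGMP each had 18 lines in wild type and 24 in Mof +/-. Counting each barcode of a layout 1 time gave 60 LT-HSC in wild type and 90 in Mof +/-, and 24 against 36 for each of the 4 populations preMEP, preCFU, MEP and proE. Counted in lines, the whole difference came from 1 wild-type progenitor layout, in which 96 of 192 lines had no primer. By distinct barcode, that layout held 96, as did the other wild-type layout and 1 Mof +/- layout. The remaining Mof +/- layout held 192. The other wild-type progenitor layout was identical to a Mof +/- layout.

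**Figure D1:**
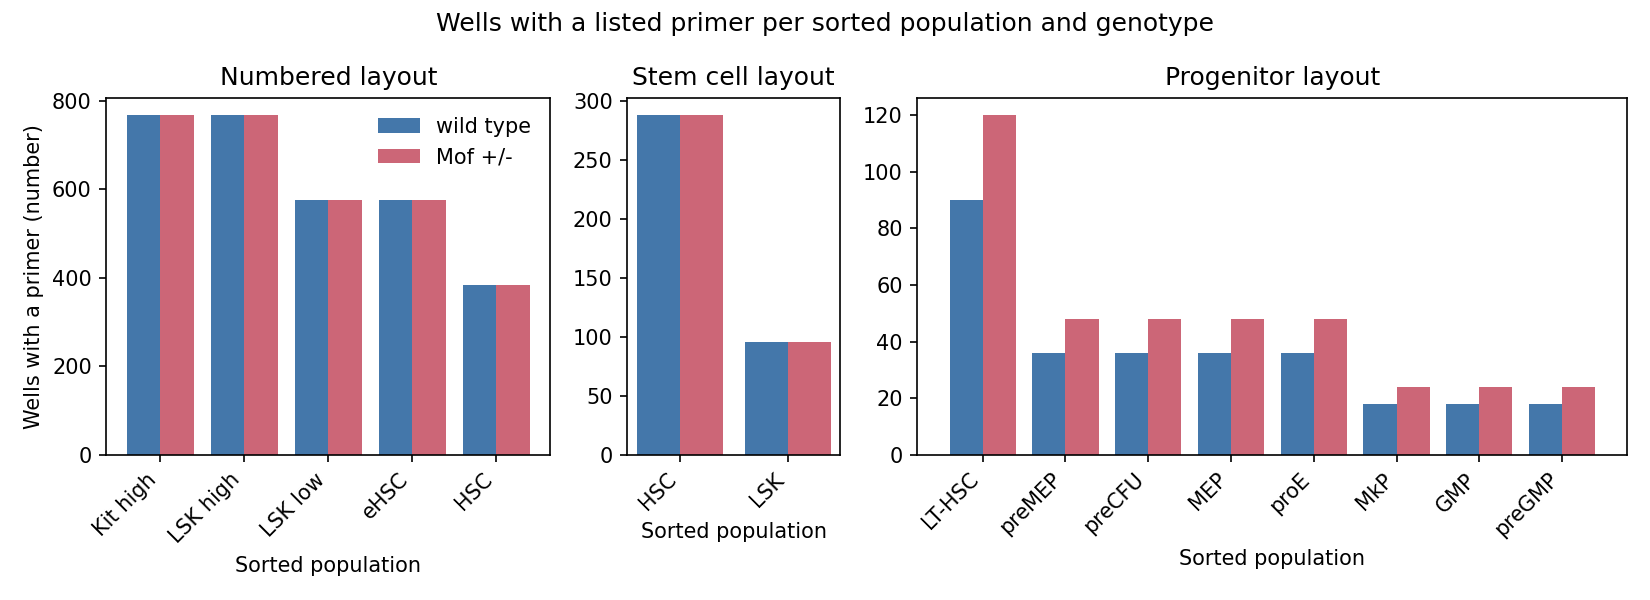
Bars give the number of wells, counted as lines with a listed primer (vertical axis, with its own scale in each panel) per sorted population (horizontal axis) in wild type and Mof +/-, for the numbered, stem cell and progenitor layouts. The genotypes are level in the numbered and stem cell layouts, and wild type has 0.75 times as many as Mof +/- in each progenitor population.

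The same stem cell gate (LSK without CD34, Flt3 and CD48, with CD150) was written in all 3 kinds of layout, as HSC or LT-HSC. Over all layouts it received 762 wells in wild type and 792 in Mof +/-, or 588 and 618 when each barcode of a layout is counted 1 time. No cells were counted here, so the limits that follow are what a count of 0 would allow, approximately, at 95% confidence. If every well gave a cell, 0 of 384 HSC wells of the numbered layouts would allow a share of up to 0.781% of cells in either genotype. For MEP, 0 of 36 wells in wild type would allow up to 8.33% and 0 of 48 wells in Mof +/- up to 6.25%. For MkP, 0 of 18 and 0 of 24 wells would allow up to 16.7% and 12.5%. These limits cover counting error only, not the spread between animals, since no label ties a sample to an animal. Wells that shared a barcode would widen the limits: with each barcode counted 1 time, the limit for MEP is 12.5% in wild type and 8.33% in Mof +/-.

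The next comparison asks whether the genotypes were given the same number of cell barcodes per layout. Wild type had a mean of 187.2 ± 21.5 primers per layout (SD, n = 20) and Mof +/- had 192 ± 0 (SD, n = 20). The difference, Mof +/- minus wild type, was 4.8 primers per layout. Layouts copy a plan and are not replicates, and any split of these values into groups of 20 gives a difference of this size, so a permutation test cannot decide it. The difference rested on 1 layout: without the wild-type progenitor layout that lacks primers, the difference was 0. Over all layouts, 3744 primers were listed in wild type and 3840 in Mof +/-. With each barcode of a layout counted 1 time, these totals were 3456 and 3552. The means per layout were then 172.8 ± 39.4 in wild type and 177.6 ± 35.2 in Mof +/- (SD, n = 20 each), also a difference of 4.8. Each primer was 82 nucleotides long. It held an adapter of 45 nucleotides with the T7 promoter, a unique molecular identifier of 6 random bases, a cell barcode of 6 bases, 24 T and a final V. The identifier has 4096 possible sequences, so 100 molecules of a gene in 1 cell would be expected to show 98.8 distinct identifiers, and 1000 molecules 887.

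The barcode sets of the genotypes were then compared. All 192 barcodes were shared in each of the 256 pairs of a wild-type and a Mof +/- numbered layout. In these 32 layouts each barcode also marked the same population on every plate. Barcode and population were thus confounded within these plates, while barcode and genotype were not. The stem cell layouts used a set of 96 barcodes, 59 of which were also in the numbered layouts. The progenitor layouts used that same set, a second set of 96 that shared 0 barcodes with it, or both. All 96 barcodes of the second set were in the numbered layouts. Over all layouts, 229 distinct barcodes occurred out of 4096 possible.

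Barcodes of a set differed from each other at 2 or more of 6 positions. In the numbered layouts the smallest number of mismatches between barcodes was 2 and the median was 4, over 18336 pairs. Of these, 0 pairs had fewer than 2 mismatches and 1056, or 5.76%, had exactly 2. In the stem cell layouts, 384 of 4560 pairs (8.42%) had exactly 2. A single substitution therefore never turned a listed barcode into another of its layout. It did give a sequence at 1 mismatch from more than 1 barcode in 2460 of 3456 possible substitutions (71.2%) in the numbered layouts and in 1536 of 1728 (88.9%) in the stem cell layouts.

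**Figure D2:**
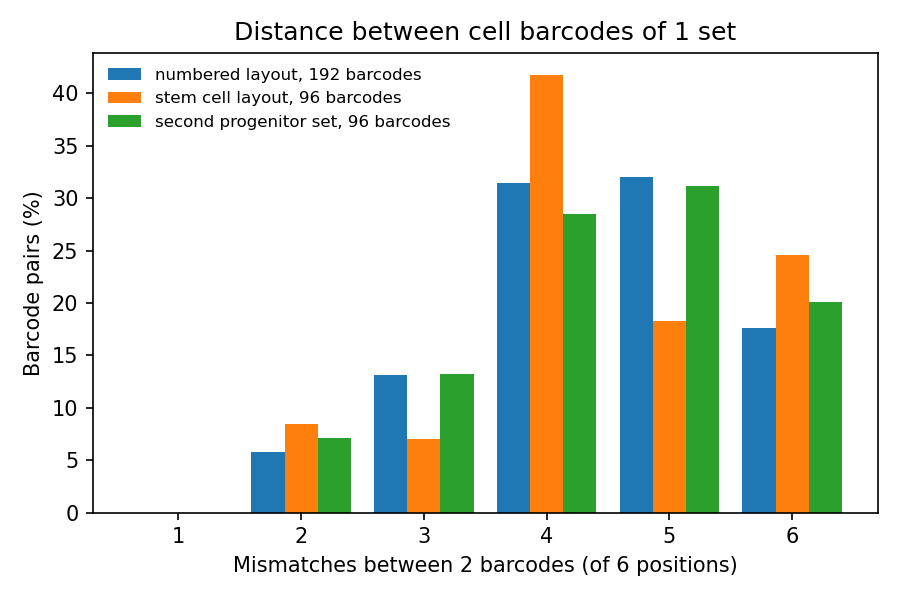
Bars give the percentage of barcode pairs (vertical axis) at each number of mismatches out of 6 positions (horizontal axis) for the 192 barcodes of the numbered layouts, the 96 of the stem cell layouts and the second set of 96 in the progenitor layouts. Each set has 0 pairs at 1 mismatch, and the shares at 2 mismatches are 5.76%, 8.42% and 7.11%.

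Base composition was compared between the genotypes last. Every layout of either genotype had a mean barcode GC content of 50% (SD 0 over 20 layouts per genotype), a difference of 0 that leaves nothing to test. Within the numbered layouts each of the 192 barcodes had a GC content of 50%. At the last barcode position, next to the run of T, T was used in 0% of the numbered barcodes, G in 31.8% and C in 31.25%, and A in the rest. The largest differences between genotypes in the mean share of a base at a position, Mof +/- minus wild type, were 0.26 percentage points for A and -0.26 for G, both at position 5. Without the wild-type progenitor layout that lacks primers they were 0.0685 and -0.134, and the largest difference was then 0.195, for T at position 5.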

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

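The tests in this part were chosen after the result was seen. Of the 4 progenitor layouts, 1 wild-type layout stood apart with 96 lines that list a primer, against 192 in each of the others. With the other 3 values equal, any different value would stand apart in this way, and these are planned numbers rather than measurements, so no chance rate applies. Its 96 listed primers match, in order, the first part of a Mof +/- layout, and its 96 other lines have a genotype and a gate but no well, primer or population.

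A candidate explanation is that the sheet was left incomplete while all wells were sorted. The gates of the 96 lines without a primer matched those of the Mof +/- layout in order, 96 of 96. Wells planned but never filled would leave the same gates, so both readings stay open. No biological explanation was tested: each genotype had 2 progenitor layouts, and only 1 of the wild-type layouts lacks primers.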

How the results depend on the processing

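The difference of 4.8 primers per layout was 4.8 when distinct barcodes were counted. It was 0 in the numbered layouts only and, in alternatives chosen after seeing the data, 0 when lines without a primer were counted and 0 without the layout that lacks primers. In listed primers, 1 layout carries the whole difference. Leaving that layout out was not tried with distinct barcodes. Of these, 1 Mof +/- progenitor layout held 192 and each of the other progenitor layouts 96. The stem cell and numbered layouts shared 59 barcodes, and 95 when the reverse complement was counted too. Allowing 1 mismatch also gave 59, as it must, because 0 pairs of the pooled barcodes are at 1 mismatch. The smallest distance was 2 by mismatches, by edits, over all layouts pooled and, in an alternative chosen after seeing the data, in the stem cell layouts. The number of pairs at that distance was 1056 in the numbered layouts, 1446 by edits, 1463 pooled and 384 in the stem cell layouts, which hold fewer barcodes. The GC difference of 0 is also 0 with each distinct barcode counted 1 time per genotype, which says nothing about stability because all layouts have a mean of 50%. Also without the layout that lacks primers, the differences in base share at position 5 moved from 0.26 to 0.0685 for A and from -0.26 to -0.134 for G, in percentage points.

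No paired analysis was possible because the layouts hold no measured value per sample. Other settings planned for genes, gene lists and cell shares (another normalization, another count test, no filter, cells of at least 1000 molecules, an estimated correlation, and other clustering resolutions) were not run, since the tables hold no gene counts. What depth limits was not analysed.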

Other observations

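The tests of reverse complements, of barcodes listed 2 times and of gates on either side of Sca-1 were chosen after the result was seen, and the other tests in this part were written before it. Among the gates of the progenitor layouts, MkP was gated as negative for CD150 and positive for CD41 in all 4 of them, and proE as negative for CD71 and CD44 and positive for Ter119.

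Of the 96 barcodes in the stem cell layouts, 72 had their reverse complement in the same set, which makes 36 pairs. The numbered layouts held exactly 1 member of each of these 36 pairs, and 0 of their 192 barcodes had a reverse complement in the set. A random draw of 59 of the 96 barcodes would keep both members of 13.5 pairs on average, and 5 or more in every one of 100000 draws, against 0 observed (one-sided permutation p = 1e-05, the smallest these draws can give). The 0 observed follows from the absence of such pairs in the whole numbered set, so the p-value restates that absence. A candidate explanation is that 1 member of each pair was removed when the set for the numbered layouts was made. The draws cannot tell this from another way of making that set. Of the 24 barcodes without a partner, 23 were kept.

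In 6 layouts, the 4 stem cell layouts and 1 progenitor layout of each genotype, each of 96 barcodes was listed 2 times. The lines of the second part repeated the barcode and the population of the first part in order, 96 of 96 in each layout. Further wells that received the same primers, or a list copied a second time, could both give this, and the layouts do not decide between them. The number of wells in these layouts is open to the same extent, so the ratio of wild type to Mof +/- per progenitor population is 0.75 with all lines counted and 0.667 with each barcode counted 1 time. No biological explanation was tested.

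Barcodes could have been placed on the plate by sequence similarity, so that misread barcodes stay within a population. Of the 1056 barcode pairs at 2 mismatches in the numbered layouts, 80.1% joined wells of different populations, against a mean of 79.3% with populations permuted over barcodes (95% of permutations between 76.9% and 81.6%, two-sided p = 0.541). Most pairs at 2 mismatches were thus not kept within a population. The share was also within the 5 percentage points set beforehand as the bound against such a placement. Any share in the permuted range would be, so the bound adds nothing to the test. The populations repeat every 16 wells, 12 times per layout, so barcodes placed by similarity along the plate could also join different populations. The test does not address such a placement, and how the barcodes were placed otherwise is not shown. Whether populations were given barcodes of different GC content had no test: the range over the 5 populations was 0, but all 192 barcodes have a GC content of 50%, so any placement gives 0.

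Barcodes were not reserved for a sort population across layouts. Of the 59 barcodes shared by the numbered and the stem cell layouts, 16 marked a Sca-1 positive gate in the stem cell layouts and Kit high, a Sca-1 negative gate, in the numbered layouts. Of these 16, 10 marked HSC in the stem cell layouts. The stem cell layouts held no Sca-1 negative gate, so every shared Kit high barcode had to change sides. The 16 therefore does not measure how often a population was kept. Of the 59, 42 marked HSC in the stem cell layouts and 6 in the numbered layouts, and 4 marked HSC in both. Whether HSC was kept more often than chance could not be tested, since the smallest one-sided p that these totals allow in a permutation test is 0.116.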
